A study of Mus musculus with 6 samples.

How the data were processed

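Expression was measured in primary mammary epithelial cells prepared by dissociating the mammary glands of 8-week-old female mice of mixed 129sv/C57Bl6 background. The labels give 3 samples wild type for Plk2 and 3 samples null for Plk2, each on its own array. Per the labels' protocols, RNA was extracted with Trizol, amplified and labelled with Cy3. Per the file headers, the arrays were of Agilent design 028005, annotated on the mm9 build, and were read with Agilent Feature Extraction 11.0.1.1 under protocol GE1_1100_Jul11. Each array holds 62976 spots, of which 3671 are controls and 59305 are gene spots carrying 55681 distinct probes.

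The intensity used here is the processed signal of each spot, a linear brightness that the scanner software had corrected for background, per the file headers; the deposited scanner values were not normalized between arrays. The deposited median spot and local background intensities served only for an alternative background correction. Flags for spots well above background, saturated or outlying were deposited beside the signals. A further deposited table of the whole series holds quantile-normalized intensities of the same arrays, an unadjusted p-value per row, a ratio of wild type over null and a signed fold given as a score by the authors. Its tools and the details of its normalization are not given in the sources used here. From the values, the columns have the same rank order as median minus background signal, with a rank correlation of 1 for the lowest of the 6 arrays, share a common distribution and lie a median of 50 units higher. The deposited p-values equal those of an equal-variance test of the log2 values to within 1.1e-08. That table served as an alternative source of values.

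Each array's log2 processed signal was centred on its 75th percentile over gene spots. Control spots were left out, as were 1119 gene spots marked as outliers over the 6 arrays, and no spot was saturated. Spots of the same probe were averaged. Gene names came from matching each probe's accession, without version, to the transcripts of a RefSeq gene table on the GRCm38.p6 assembly, which was used only for names and for which genes lie near each other; 26582 of the 55681 probes matched, for 20145 genes. Probes well above background on at least 3 of the 6 arrays were kept, whatever their group. For each gene the probe with the highest mean over the 6 arrays was used, and an unmatched probe stood for itself. This left 24609 entries for testing, 14417 with a gene symbol and 10192 without, with 40 missing values. Of the named genes on the array, 3701 had at least 2 kept probes. A total of 17 further probes belonged to 16 of the genes called below, and 16 of these 17 had the same sign as the probe reported. Sizes differed for some: the other probe gave -0.089 against -2.58 for Sh2d2a, -0.23 against -2.01 for Cpne1 and, with the opposite sign, 0.12 against -1.35 for Rprd1b.

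Differences are null minus wild type on the log2 scale, tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A total of 28 gene lists with 633 gene names were tested with camera of limma at a preset correlation between genes of 0.01, again with Benjamini-Hochberg adjustment. The correlation was also estimated from the data, and the lists were tested with fry. Where a probe was not well above background on any array of a group, only a bound is given: the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest value among probes well above background. A p-value beside a bound is that of the difference between the unbounded values and does not test the bound. The text names Plk2, the 12 genes with a symbol and the largest difference in each direction among those past the threshold whose groups did not overlap, the 4 members of each list with the smallest p, and a fixed set of kinase, hormone receptor and lineage genes. Some genes that this rule takes are not reported here. The design, the lists, this rule and the main alternatives were fixed before the data were examined. Arrays' own measures were compared with 2-sided exact permutation tests, which with 3 arrays against 3 cannot give a p under 0.1.

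Alternatives were another background correction (normexp with an offset of 50, on the median signal because the mean signal is not among the columns used here), quantile normalization, median centring, other filters, the mean of a gene's probes, other moderation, array weights, the replicate number as a block, each array left out in turn, the deposited table's values and a minimum fold of 1.2. Scaling on spike-in controls, an equal-variance test and a looser threshold were added after the data were seen. The steps were tested on simulated arrays of 24609 entries with 50 changed genes of each size: for this comparison, 16% were recovered at a log2 size of 1, 80% at 2, 92% at 3 and 98% at 4, with 1 false call. The simulated genes varied independently, and with no gene changed 0 of the 28 lists were called, so the simulation does not cover correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All 6 arrays lay on 1 slide, so slide was not used as a block. Each sample's title begins with a different number, but the labels do not say whether these numbers stand for separate animals. The numbers of the null samples are consecutive and those of the wild-type samples are not. The p-values therefore measure the spread between these samples, which may be technical.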

Results

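The series compared mammary epithelial cells of 3 Plk2 null and 3 wild-type samples, and so asks which transcripts differ when Plk2, a polo-like serine/threonine kinase, is missing. Between 50.2% and 52.2% of probes were well above background on the wild-type arrays and between 51.2% and 54.7% on the null arrays. The mean number of such probes was 28390 ± 604 (SD, n = 3) in wild type and 29430 ± 991.5 (SD, n = 3) in null samples, a difference that an exact permutation test did not separate (p = 0.2; smallest possible 0.1). Array values correlated at 0.987 to 0.990 across genes within wild type, 0.975 to 0.989 within null and 0.960 to 0.980 between groups. Null sample 3 lay apart from the other arrays on the second principal component (23.5% of the variance), at 74.0 against -26.5 to 2.88. All wild-type arrays lay in row 1 of the slide and all null arrays in row 2, so slide row and genotype cannot be told apart. The number of arrays limits the precision of every value below.

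Plk2 was measured by a single matched probe (NM_152804, chromosome 13). It was well above background in all 3 wild-type samples, with processed signals of 1160 to 1472, and not well above background in any null sample, with signals of 1.88 to 2.44. The log2 level was 2.26 ± 0.10 (SD, n = 3) in wild type and -7.06 ± 0.12 (SD, n = 3) in null cells. Plk2 was therefore at least 149.8-fold lower in null cells (limma, adjusted p = 3.61e-06). The deleted part of the gene is not given in the sources used here, so whether the probe lies inside it is open. Among related kinases, Plk1 differed by 1.68 (SE 0.47; limma adjusted p = 0.115), Plk4, well above background on 1 of 3 wild-type arrays, by 1.60 (SE 0.37; adjusted p = 0.0887) and Plk3 by -0.39 (SE 0.17; adjusted p = 0.226), none of them past the threshold.

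Across all entries, 56 rose and 83 fell in null cells (limma, adjusted p under 0.05), of which 30 and 47 have a gene symbol. Spink1, which encodes a secreted inhibitor of trypsin-like proteases, showed the largest rise among named genes past the threshold whose fold is not a bound, from -2.01 ± 0.32 to 3.80 ± 0.88 (SD, n = 3 each; 55.8-fold, limma adjusted p = 0.00898). Slc5a7, a choline transporter, was not well above background in wild type and was at least 5.63-fold higher in null cells (adjusted p = 0.000922). Drd4, a dopamine receptor, was at least 3.18-fold higher, and Slc35d3 and Ccdc150 were at least 3.24-fold and 1.37-fold higher, by the same kind of bound. Abcg5, a subunit of a sterol transporter, rose 7.34-fold and the acute phase gene Saa2 7.05-fold. The kinetochore gene Spc25 rose 5.74-fold, Adat2, a subunit of a tRNA deaminase, 5.09-fold, Pnma2 5.28-fold and the cation channel gene Trpm1 4.48-fold. Adjusted p-values of these genes lay between 0.000922 and 0.0479. Saa2 has a near-identical neighbour, Saa1, and the values of both are uncertain for that reason.

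Among named genes past the threshold whose fold is not a bound, the deepest falls were in Aoc1, which encodes diamine oxidase, from 4.12 ± 1.82 to -2.49 ± 0.49 (SD, n = 3 each; 97.6-fold, limma adjusted p = 0.0403), and Ptpn5, a tyrosine phosphatase gene, from 1.70 ± 0.96 to -4.78 ± 0.32 (89.5-fold, adjusted p = 0.00883). The fold of Aoc1 was 49.6 without wild-type sample 1, where that of Ptpn5 was 62.3, and 172.3 without wild-type sample 3. Ptpn5 was well above background on 2 of the 3 null arrays. Zfhx3, a homeobox transcription factor gene, was at least 12.5-fold lower, Zc3h12d at least 5.82-fold and Ceacam13, by the reported probe, at least 4.95-fold. Sh2d1a, an adaptor of T and NK cells, was at least 5.51-fold lower and Gpr174, a receptor of lymphocytes, at least 3.00-fold. Fermt1, which encodes the integrin adaptor kindlin-1, was at least 3.26-fold lower and Hyal3 at least 2.17-fold. The cytochrome gene Cyp3a25 fell 9.46-fold and Slc52a3, a riboflavin transporter gene, 8.26-fold. Adjusted p-values of these genes lay between 0.00253 and 0.0479. Of the 26 named genes called, Plk2, Mcm3 and Pgr included, 15, 21 and 13 were not called without wild-type sample 1, 2 or 3, and 21, 12 and 0 without null sample 1, 2 or 3.

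**Figure D1:**
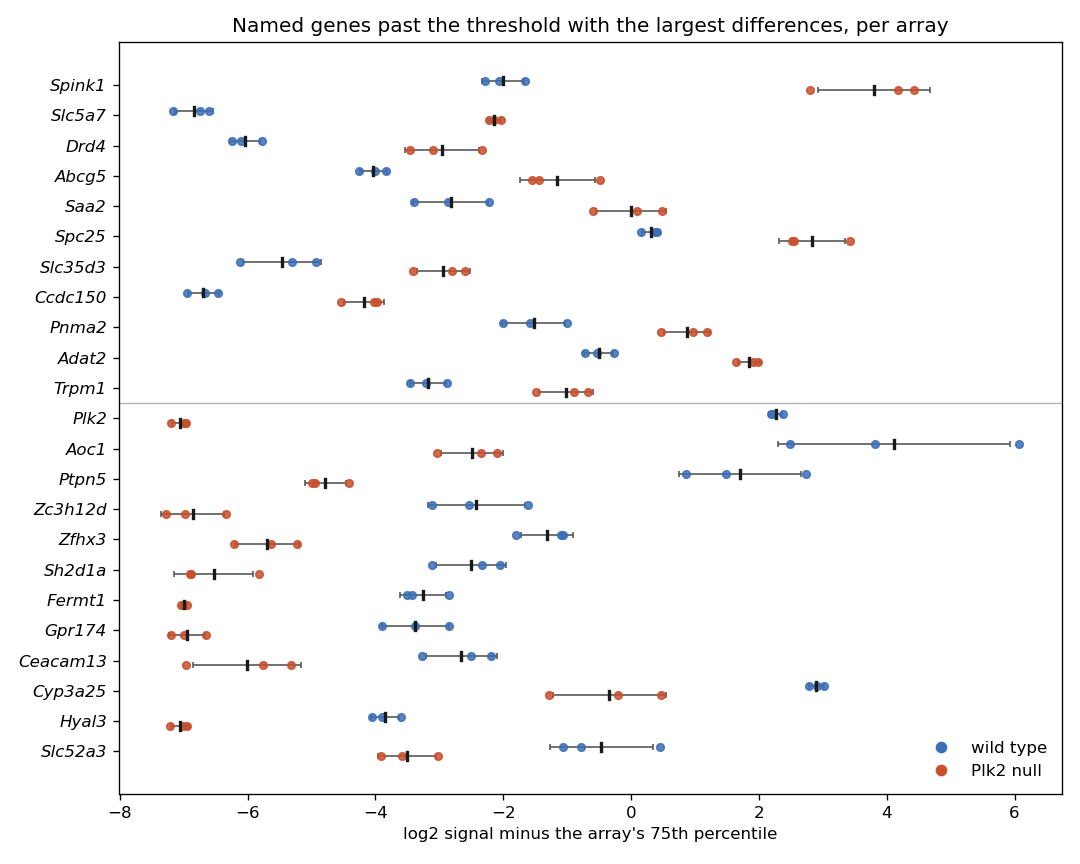
Log2 signal relative to each array's 75th percentile, per array, for named genes past the threshold with the largest rise (top) and fall (bottom); points are arrays, black ticks group means and bars SDs over 3 arrays. The null arrays lie wholly on one side of the wild-type arrays for each gene shown, and Plk2 sits at -7.06 in null against 2.26 in wild-type cells.

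At an adjusted p under 0.1, 892 entries were higher and 747 lower, and at an unadjusted p under 0.05 the counts were 3322 and 2347. The arrays of both groups did not overlap for 7769 entries, or 31.6%, against the 10% that chance gives. The split of calls differed between scalings: 179 rose and 167 fell with each array centred on its median, 157 and 117 with spike-in scaling, and 41 and 68 with quantile normalization. The deposited table's values, which differ in background correction too, gave 387 and 381. Spike-in scaling moved the median difference of all entries from 0.03 to 0.29, and the share that was higher among those with an unadjusted p under 0.05 from 58.6% to 85%. Leaving out null sample 3 gave 239 higher and 465 lower, whereas leaving out wild-type sample 1, 2 or 3 gave 5, 1 or 13 higher and 24, 6 or 30 lower, and leaving out null sample 1 or 2 gave 1 or 17 higher and 6 or 29 lower. In the authors' deposited table, 921 rows passed both of its thresholds (unadjusted p of 0.01, fold of 1.4), 488 higher and 433 lower in null cells, and 114 of the 139 probes called here are among them.

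**Figure D2:**
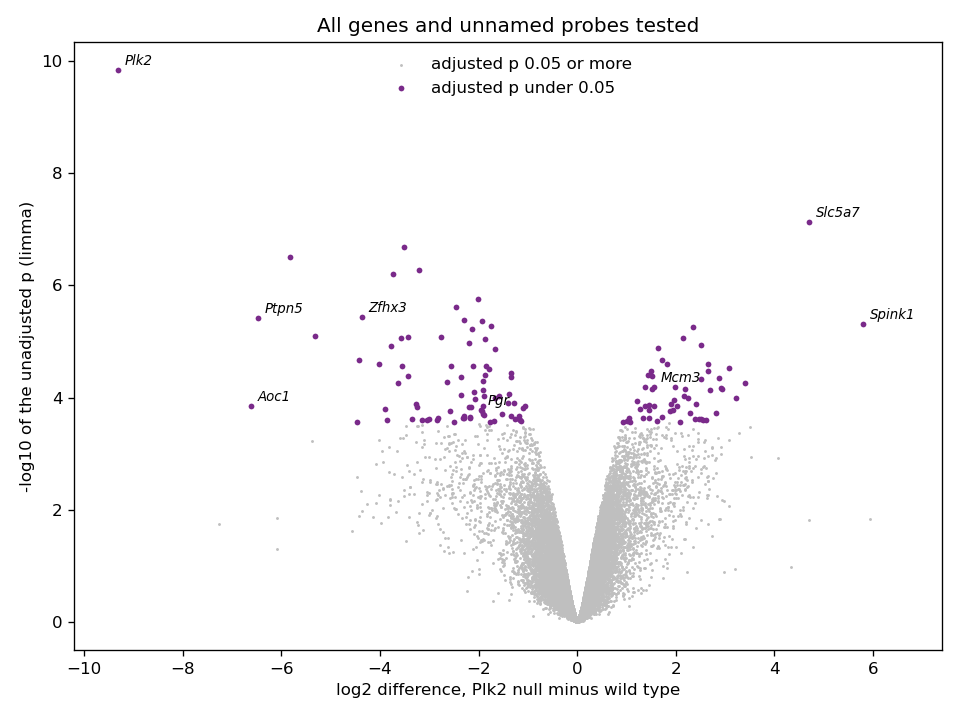
Log2 difference between null and wild-type cells (horizontal) against the negative log10 of limma's unadjusted p (vertical) for all 24609 entries; purple points passed an adjusted p of 0.05. There are 56 such points to the right of 0 and 83 to the left, with Plk2 alone at -9.32.

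Genes of cell division were higher in null cells. All 28 measured genes of mitosis had a positive difference, with a median of 1.95 (camera adjusted p = 2.31e-13; adjusted p = 0.497 with an estimated correlation); 25 passed adjusted over the list alone and 0 over all genes (limma; 25 at an unadjusted p under 0.05). The spindle checkpoint kinase gene Bub1 differed by 2.56 (SE 0.47), the microtubule-binding Nusap1 by 2.39 (SE 0.47), Melk by 2.55 (SE 0.51) and Birc5, which encodes survivin, by 2.34 (SE 0.46). All 34 genes of DNA replication were likewise positive, with a median of 1.23 (camera adjusted p = 5.46e-13; adjusted p = 0.497 with an estimated correlation), 27 of them past the threshold adjusted over the list alone and 1 over all genes. That gene, Mcm3, a subunit of the replicative helicase, rose 2.94-fold (limma adjusted p = 0.0288). Mcm3 was not called in 7 of 17 alternatives. Gins2 differed by 1.29 (SE 0.23), thymidine kinase Tk1 by 2.21 (SE 0.45) and the primase gene Prim1 by 1.57 (SE 0.32). Centrosome genes had a median of 0.45 with 22 of 25 positive (camera adjusted p = 9.01e-05; adjusted p = 0.542 with an estimated correlation), and none passed adjusted over the list alone or over all genes (limma; 13 at an unadjusted p under 0.05). The mitosis list's median lay at 1.36, 3.12 and 1.48 above the wild-type mean in null samples 1, 2 and 3, and the centrosome median was 0.29 without null sample 2 and 0.71 with spike-in scaling. In the same samples lymphocyte markers had a median of -2.41.

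Markers of lymphocytes were lower in null cells, the widest shift among the lists of other cell types. The list's median was -2.41 over 23 genes (camera adjusted p = 3.36e-11; adjusted p = 0.497 with an estimated correlation). Adjusted over the list alone, 20 genes were lower and 1 higher, and 0 passed over all genes (limma; 21 at an unadjusted p under 0.05). The B cell receptor gene Cd79b differed by -2.49 (SE 0.43), Jchain, which joins immunoglobulin chains, by -2.60 (SE 0.45) and the T cell receptor gene Cd3e by -2.11 (SE 0.38). The list's median lay at -2.82, -3.13 and -1.32 in null samples 1, 2 and 3. In the same samples fibroblast genes had a median of -0.49, negative in 24 of 24 (camera adjusted p = 1.48e-06; adjusted p = 0.497 with an estimated correlation), Schwann cell genes -0.58 (0.00012; adjusted p = 0.497 with an estimated correlation), endothelial genes -0.41 (0.000258; adjusted p = 0.586 with an estimated correlation), macrophage and myeloid genes -0.46 (0.00279; adjusted p = 0.699 with an estimated correlation) and pericyte genes -0.36 (0.0321; adjusted p = 0.699 with an estimated correlation). Thy1 is in both the lymphocyte and the fibroblast list. Of the fibroblast genes, Sfrp2 differed by -0.63 (SE 0.18) and Col6a2 by -0.67 (SE 0.20). Adjusted over the list alone, 4 Schwann cell and 2 pericyte genes passed, all lower, and none of the fibroblast, endothelial or myeloid genes. An unadjusted p under 0.05 by limma was reached by 4 of 20 endothelial, 5 of 23 myeloid and 3 of 12 pericyte genes. These shares lie near the 23% of all entries. For fibroblast and Schwann cell genes the counts were 10 of 24 and 6 of 13, above that share. In null sample 3 the endothelial, pericyte and myeloid medians lay at -0.0017, 0.063 and -0.069 from the wild-type mean, within the range of the wild-type arrays, against -0.31, -0.25 and -0.32 in null sample 1 and -0.81, -0.69 and -0.76 in null sample 2. The myeloid list was not called without wild-type sample 1 (median -0.17, camera adjusted p = 0.152) or null sample 2 (-0.17, 0.0755). The pericyte list was not called in 9 of 19 alternatives, among them those without wild-type sample 2 or 3 or null sample 1 or 2 (highest camera adjusted p of these = 0.326, median -0.11). The lowest adjusted p over their alternatives was 0.000172 for myeloid and 0.00249 for pericyte genes. The endothelial median was -0.25 without null sample 2 and the Schwann cell median -1.10 without null sample 3. With spike-in scaling the medians were -0.23 for fibroblast, -0.32 for Schwann cell, -0.15 for endothelial, -0.20 for myeloid and -0.11 for pericyte genes, the last no longer called (camera adjusted p = 0.094). Erythroid (median -0.13), adipocyte (0.19) and skeletal muscle genes (-0.15) were not called.

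**Figure D3:**
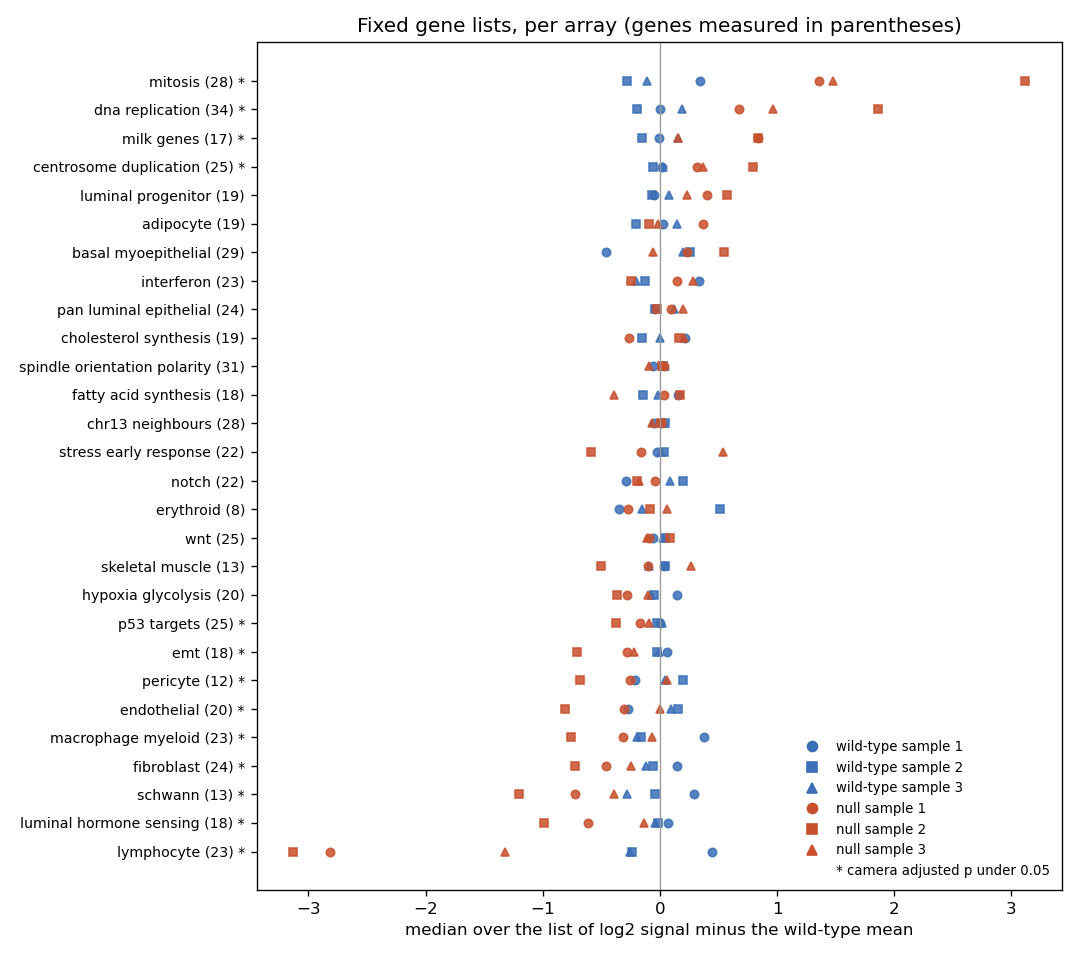
Median over each fixed gene list of log2 signal minus the wild-type mean (horizontal), for each of the 6 arrays; symbols mark samples 1, 2 and 3 of each group, and asterisks mark lists with a camera adjusted p under 0.05. Null sample 2 lies farthest from wild type for mitosis, at 3.12, and for lymphocyte genes, at -3.13.

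Among epithelial lineages, genes of hormone-sensing luminal cells fell, with a median of -0.69 and 15 of 18 negative (camera adjusted p = 0.000385; adjusted p = 0.497 with an estimated correlation). Pgr, the progesterone receptor gene, fell 3.88-fold (difference -1.96, SE 0.26, limma adjusted p = 0.043), and its other kept probe gave -2.33. Pgr was not called in 8 of 17 alternatives. It was the only list member past the threshold over all genes, while 6 were lower and 1, Calca, higher adjusted over the list alone. Greb1, an oestrogen target, differed by -2.76 (SE 0.46), Tnfsf11, which encodes RANKL, by -2.99 (SE 0.86), Msx2 by -0.86 (SE 0.23) and the oestrogen receptor gene Esr1 by -0.91 (SE 0.27; limma adjusted p = 0.122). Calca, at 4.71 (SE 1.44), was chosen after its value was seen. The list's median lay at -0.61, -0.99 and -0.14 from the wild-type mean in null samples 1, 2 and 3. It was -0.39 without null sample 2 and -0.44 with spike-in scaling, and lymphocyte markers had a median of -2.41 in the same samples. Milk genes had a median of 0.74 with 14 of 17 positive (camera adjusted p = 0.0151; adjusted p = 0.497 with an estimated correlation), and 3 passed adjusted over the list alone, Fabp3 (0.82, SE 0.14), the mucin gene Muc15 (2.27, SE 0.43) and the lipase gene Cel (1.28, SE 0.26). The casein gene Csn1s1, well above background on 2 of 3 wild-type arrays, differed by 5.94 (SE 1.81; limma adjusted p = 0.131). The milk list's median lay at 0.84, 0.84 and 0.16 in null samples 1, 2 and 3, and at up to 0.15 in wild type. The milk list was not called without null sample 1 (camera adjusted p = 0.0603) or with spike-in scaling (0.117), against a lowest value of 8.49e-05 over its alternatives, and its median was 0.47 without null sample 2 and 0.46 with the deposited table's values. Luminal progenitor genes had a median of 0.38 and were not called (camera adjusted p = 0.122; 0.00646 without the filter on dim probes), with 13 positive and 6 negative members, of which 3 were higher and 1 lower adjusted over the list alone. Elf5, a transcription factor of the alveolar lineage, differed by 1.71 (SE 0.29; limma adjusted p = 0.0571) and the retinaldehyde dehydrogenase gene Aldh1a3 by -1.59 (SE 0.35; adjusted p = 0.0833). Pan-luminal genes (median 0.08; camera adjusted p = 0.839) and basal genes (0.15; 0.434) were not called. The basal list was called without the filter (0.0381) and without wild-type sample 2 (median 0.34, camera adjusted p = 0.0402). Keratin genes differed by 0.97 (SE 0.43) for Krt5, 0.92 (SE 0.34) for Krt14, -0.10 (SE 0.17) for Krt8 and 0.06 (SE 0.15) for Krt18, none past the threshold. The signs of Krt8 and Krt18 changed with the scaling, to 0.16 with spike-in scaling and to -0.02 with quantile normalization.

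Genes of the epithelial-mesenchymal transition fell, with a median of -0.36 and 15 of 18 negative (camera adjusted p = 0.00221; adjusted p = 0.497 with an estimated correlation). Adjusted over the list alone 4 were lower: the transcription factor genes Foxc2 (-1.37, SE 0.33), Twist2 (-0.68, SE 0.18) and Zeb1 (-0.75, SE 0.21), and the matrix protease gene Mmp2 (-0.83, SE 0.23). Fibroblast genes had a median of -0.49 in the same samples. The transition list's median was -0.22 without null sample 2 and -0.10 with spike-in scaling. Targets of p53, a list without Plk2, had a median of -0.22 (camera adjusted p = 0.0368; adjusted p = 0.497 with an estimated correlation), and none passed adjusted over the list alone or over all genes (limma; 6 of 25 at an unadjusted p under 0.05). Over all entries 23% had an unadjusted p under 0.05 by limma, a share near that of the p53 targets. Gadd45a differed by -0.60 (SE 0.15) and Gdf15 by -1.09 (SE 0.34). The p53 list was, among other settings, not called without wild-type sample 1 (median -0.06), null sample 1 (-0.23) or null sample 2 (-0.12), and its median turned to 0.03 with spike-in scaling. Camera adjusted p-values over its alternatives ran from 0.0122 to 0.497. Genes of spindle orientation and cell polarity were not called (median 0.04, camera adjusted p = 0.969), Gpsm2 having the smallest p among them with a difference of 0.83 (SE 0.23). Also not called were genes of Notch signalling (median -0.11), Wnt signalling (-0.13), the interferon response (0.09), hypoxia and glycolysis (-0.20), cholesterol synthesis (0.06), fatty acid synthesis (0.02) and the early stress response (-0.08), with camera adjusted p-values from 0.0578 to 0.967. Of these, the hypoxia list was called in 8 of 19 alternatives (camera adjusted p from 0.00646 to 0.586), among them those without wild-type sample 2 (median -0.098), wild-type sample 3 (-0.22) or null sample 3 (-0.26). The Notch list was called in 3 (from 0.00333 to 0.699), among them that without wild-type sample 1 (median -0.31), and the early stress list in 3 (from 0.000166 to 0.951), among them that without null sample 3 (-0.37). The early stress median lay at -0.17, -0.59 and 0.54 in null samples 1, 2 and 3. The median and the mean differ in sign for the Wnt, cholesterol and fatty acid lists, and the median and the camera direction for the spindle, interferon, cholesterol and fatty acid lists. Over the 28 lists, 64 of 586 genes passed adjusted over the lists' union, 38 higher and 26 lower, and 2 of them, Mcm3 and Pgr, over all genes.

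Because the mice were of mixed strain background, genes within 20 Mb of Plk2 on chromosome 13 were tested as a group. Of 131 such genes 1 was called (0.763%), against 75 of 14285 other named genes (0.525%; 2-sided Fisher's exact test, p = 0.501). Their median difference was 0.06, and camera did not call them as a group. A list of neighbouring genes written from memory beforehand was not called either (median -0.03, camera adjusted p = 0.624).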

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

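Spike-in scaling, the equal-variance test and the looser adjusted p were chosen after the data were seen. Plk2 was called under every alternative that gave a value, from -9.36 to -4.49, and was not tested where a signal well above background on all 6 arrays was required. Fermt1, Hyal3 and Slc5a7 also kept their calls in each alternative that gave one. Among the 26 named genes called, 297 values of 429 stayed past the threshold and 132 did not. Among called lists 201 of 247 stayed, 45 did not and 1 reversed. Of all 139 entries called, 7 stayed without wild-type sample 2 and 7 without null sample 1. With the replicate number as a block 8 stayed, and 25 without a filter on dim probes. With median centring 138 stayed, and with array weights all 139. Genes near Plk2 were not called by camera under any alternative run. Slide as a block was not run, since all arrays lay on 1 slide. Low signal over background limits the folds given as bounds. The cause of the changes was not tested unless stated.

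Counts of higher and lower entries were 718 and 514 with normexp, 179 and 167 with median centring, 204 and 176 with all 6 arrays above background, 387 and 381 with the deposited values, 459 and 388 with trended robust moderation, and 668 and 706 with array weights. They were 5 and 26 without a filter on dim probes, where more entries were tested, 28 and 39 at a minimum fold of 1.2, and 892 and 747 at an adjusted p under 0.1. Spike-in scaling gave 157 higher. An equal-variance test gave 628 and 387 at the deposited table's thresholds, and 0 and 2 after Benjamini-Hochberg adjustment, where limma gave 56 and 83 (3322 and 2347 at an unadjusted p under 0.05). Leaving out a sample gave 1 to 239 higher and 6 to 465 lower, and 0 to 159 genes over the lists' union. That union count was 150 with normexp, 154 with the deposited values, 145 with trended robust moderation, 180 with array weights and 0 without the filter. Called lists numbered 0 with an estimated correlation and 0 with fry, and 10 to 16 otherwise.

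With the replicate number as a block, 2 entries were higher, 6 lower and 0 of the lists' genes called. The numbers did not pair the samples: deviations of same-numbered samples correlated across genes at -0.119, 0.0379 and -0.0183. Each null sample's best partner among the wild-type samples had another number. The correlations were -0.145 for number 3 with normexp, -0.0342 for number 1 without the filter, and -0.0498 and -0.14 for numbers 2 and 3 with the deposited values.

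Directions turned as follows, in log2. With spike-in scaling: p53 targets 0.033, Notch 0.14, Wnt 0.12, early stress 0.17, hypoxia 0.052, erythroid 0.12, skeletal muscle 0.11, Plk2 neighbours 0.23, Hba-a1 0.060, Hba-a2 0.091 and Krt8 0.16. Fatty acid genes were at -0.0061 with normexp, -0.034 with quantile normalization and -0.049 with the deposited values. Spindle genes were at -0.059 with quantile normalization, -0.048 with the mean of probes and -0.022 with the deposited values, which also gave -0.0049 for pan-luminal and -0.010 for interferon genes. Krt18 was at -0.017 with quantile normalization and -0.0091 with array weights, Wnt at 0.052 without the filter, and Plk2 neighbours at 0.0090 with median centring and 0.029 with the mean of probes. Leaving out a sample gave -0.036 to 0.041 for spindle, -0.0031 to 0.14 for pan-luminal, -0.017 to 0.39 for basal, -0.13 to 0.091 for Wnt, -0.37 to 0.12 for early stress, -0.060 to 0.29 for interferon, -0.056 to 0.16 for cholesterol, -0.12 to 0.11 for fatty acid, -0.033 to 0.31 for adipocyte, -0.30 to 0.14 for erythroid, -0.35 to 0.11 for skeletal muscle and -0.073 to 0.038 for Plk2 neighbour genes. The same ranges were -0.38 to 0.031 for Hba-a1, -0.35 to 0.078 for Hba-a2 and -0.054 to 0.13 for Krt18.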

Other observations

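The second lists of T cell, B cell and lymph node genes, the unnamed probes of chromosome 2 and the splits of the samples were tested before their values had been looked at; the other tests here, and the choice of the genes in this paragraph, came after the results were seen. Among called genes outside the fixed lists, Cd8b1, a T cell co-receptor chain, fell 7.11-fold, the phosphatase gene Ptpn22 4.24-fold, the chromatin organiser Satb1 4.57-fold and the transcription factor gene Ets1 2.25-fold (limma adjusted p = 0.0479, 0.0367, 0.0403 and 0.0479). Lymphocyte markers had a median of -2.41 in the same samples, and whether these falls came from lymphocytes or from epithelial cells was not tested. Pdk4, a kinase that holds back pyruvate dehydrogenase, rose 3.68-fold (adjusted p = 0.043) and Eci2, an isomerase of fatty acid oxidation, 2.10-fold (adjusted p = 0.0488). Saa1 rose 4.45-fold (adjusted p = 0.0103). When wild-type sample 1, 2 or 3 or null sample 1 or 2 was left out, Cd8b1, Ptpn22, Satb1, Ets1, Pdk4 and Eci2 were not called (limma adjusted p from 0.0753 to 0.164), and Saa1 was not called without wild-type sample 2 or null sample 1 (0.0623 and 0.0592).

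Some Notch and Wnt members passed adjusted over the list alone while their lists were not called. The Notch target Hes5 (-1.27, SE 0.20; well above background on 1 of 3 null arrays) and the Notch regulator Dtx1 (-1.36, SE 0.22) were lower. The Wnt list, with 12 positive and 13 negative members, had 3 higher and 3 lower: Ccnd1, a cyclin gene, was higher by 1.08 (SE 0.21), the ligand enhancer Rspo1 by 2.25 (SE 0.52) and the antagonist Wif1 by 2.13 (SE 0.52). Lef1, which T cells also express, differed by -4.47 (SE 0.95) and was well above background on 2 of 3 null arrays, and the antagonists Sfrp2 and Sfrp1, the latter chosen after its value was seen, differed by -0.63 (SE 0.18) and -0.48 (SE 0.14). None of these passed over all genes (limma adjusted p from 0.0536 to 0.12).

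Cell cycle genes were higher in all 3 null samples. An enrichment of epithelial cells would raise epithelial transcripts alike, and the pan-luminal median of 0.0772 (SD of members 0.375) lies far under the mitosis median of 1.95, which argues against that as the whole cause. Null sample 2 had the highest values, yet the mitosis median was 1.41 without it, which argues against that sample alone. Slide rows that held both groups numbered 0, so slide row, or another property the null arrays share, cannot be told apart from genotype. More cycling cells in the null samples may account for the pattern, as a hypothesis that these arrays do not test.

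Lymphocyte genes were lower in all 3 null samples. A second T cell list had a median of -2.84 over 10 genes and a second B cell list -2.24 over 9 (9 and 8 lower adjusted over the list alone, 0 over all genes by limma), so fewer T and B cells in the null samples is a candidate explanation. Less lymph node tissue, carried along in dissected glands, is another: genes of lymph node stroma and vessels had a median of -1.75 (SD of members 1.61) over the 5 measured of 8, with 2 lower adjusted over the list alone and 0 over all genes by limma, and Madcam1 differed by 0.98 (SE 0.69). The deepest falls of that list were in Chst4 (-3.26, SE 1.02) and Cr2 (-2.52, SE 0.61). Chst4 was well above background on 1 of 3 null arrays. Red cell genes had a median of -0.129 (SD of members 0.289), which argues against less blood, with Hba-a2 at -0.16 (SE 0.24). These lists do not tell fewer T and B cells apart from less lymph node tissue. Cells were not counted here, so whether the null samples held fewer lymphocytes stays open. Whether the loss of Plk2 or the dissection was the source stays open too.

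Of 77 named calls, 14 lay on chromosome 2 (18.2%), which holds 7.82% of the named genes tested (2-sided Fisher's exact test, p = 0.00235; adjusted p = 0.0469 over 20 chromosomes). That adjusted p lies close to the threshold and takes genes as independent. The test was chosen after the results were seen and was not repeated under other settings, so chance placement over chromosomes is not excluded. Of the 14 calls, 5 (Cpne1, Rprd1b, Gdap1l1, R3hdml and Serinc3, chosen after their values were seen) stood among 100 neighbouring named genes. Random placements of the calls gave as many in a share of 0.0988 of 10000 draws, so chance is not excluded for that stretch either. A stretch of another strain could also be the source, and unnamed probes on chromosome 2 had an unadjusted p under 0.001 in 0.322% against 0.985% elsewhere (2-sided Fisher's exact test, p = 0.365). The share was no higher on chromosome 2, the outcome set beforehand as going against a strain difference. It rests on 1 of 311 probes and covers the whole chromosome, so it cannot decide for the stretch. Base differences under single probes stay open too: of 4 of these genes with another kept probe, 2 (Gdap1l1 and Serinc3) differed the same way by over 0.5 log2 units by it, and Cpne1 and Rprd1b differed by -0.23 and 0.12.

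The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 56 higher and 83 lower entries and the highest of the others 0 and 0, each real count being reached in 1 of the 10 splits. Over the lists' union it gave 64 genes and the highest other 0, again 1 of 10. Each other split mixes both genotypes within its groups, so genotype differences widen its spread and lower such counts. The counts of 0 therefore do not show what groups without a genotype difference would give. For the number of called lists the real value was 13 and the highest other 18, and 5 of the 10 splits called as many or more.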
